A study of Mus musculus with 10 samples.

How the data were processed

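The study measured polyadenylated RNA in C2C12 cells, a mouse myoblast line that fuses into multinucleated myotubes when serum is lowered. Per the labels' protocols, cells were differentiated for 3 days, transduced with adenovirus encoding Arrdc2 together with Gfp or Gfp only, and harvested after 48 h. Strand-specific libraries were sequenced with paired-end reads. The 10 samples form 2 groups of 5, GFP and Arrdc2. The labels do not say whether the replicates of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

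The authors deposited a single table of regularized log values (rlog) on the log2 scale, with 57010 mouse gene identifiers and a column for each of the 10 libraries. Regularized log values are log2 read counts scaled by a size factor per library, in which each library's deviation from the gene's mean is shrunk towards 0, most strongly where reads are few. Fold changes on this scale therefore understate the change, and those of genes with few reads most. STAR 2.7.10a, DESeq2 1.30.1 and the GRCm39 build are named in the submitters' processing notes; the counting tool, the annotation release and the strand setting of the counting are not given in the sources used here. Column names give the group and a library number (3 to 7 in GFP; 6, 7, 9, 10 and 11 in Arrdc2) that does not match the replicate numbers of the labels, so each column was used as a replicate of its group with no pairing, and libraries are named below by their column number. No column was left unused.

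Gene symbols were matched by identifier, without its version, to a GENCODE vM21 gene table, and 52029 of the 57010 identifiers had a symbol. That annotation belongs to another build (GRCm38), so no positions are given, and it served otherwise only for transcript GC content and length. In the table, 24903 genes held 0 in all 10 libraries and 32107 varied. Genes with a mean rlog value of at least 3 were tested, 15223 in all, of which 14953 had a symbol. Deposited values were fitted with limma 3.58.1 in R 4.3.3 (linear model on group, empirical Bayes with a mean-variance trend), and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. "Rose" and "fell" refer to genes past that threshold. An exact 2-sided permutation test over 252 assignments was added for Arrdc2.

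Because regularized log values come from a penalised negative binomial fit, the whole read counts behind them could be solved for. Size factors, the penalty and the dispersion trend were fitted on 10698 genes and checked on 10698 held-out genes, where 99.1% of the values of genes with at least 1 read came within 0.1 reads of a whole number, against 20% by chance. The share was 100% at a mean of 1 to 10 reads and 85.5% above 10000 reads, so the counts of the most abundant genes are less exact. Recovered reads gave each library's depth, mean normalised reads per group, and folds free of the shrinkage, fitted with limma voom. This step was chosen after seeing the data; it is an alternative to the test on the deposited values and not its replacement. Folds and their 95% intervals in the text come from recovered reads, whereas log2 differences with standard errors (SE) and adjusted p-values come from the deposited values.

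Recovered depth lay between 18.93 and 28.65 M (mega) reads per library. For the 5553 genes with at least 1000 normalised reads, the median coefficient of variation within a group was 4.72%. Mean chi-square values per gene between libraries of the same group ranged from 2.65 to 17.2, so no pair agreed within sampling noise and all 10 libraries were kept as separate samples.

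Before the data were examined, 41 gene lists were fixed from textbook knowledge. They cover alpha-arrestins and beta-arrestins, NEDD4-family ligases, muscle atrophy, autophagy, proteasome, myogenic regulators, sarcomere, excitation-contraction coupling, neuromuscular junction, nuclear and mitochondrial respiratory chain genes, the citric acid cycle with fatty acid oxidation, glycolysis, cholesterol and lipid synthesis, interferon response, antigen presentation and NF-kappaB targets. They also cover ATF4, unfolded protein, heat shock, NRF2 and p53 responses, cell cycle, apoptosis, extracellular matrix, TGF-beta, insulin, beta-adrenergic, endocytosis, ribosomal protein, Notch and Wnt, clock and myoblast genes, neighbours of Arrdc2, and markers of fibroblasts, adipocytes, osteoblasts, macrophages, endothelium and neural cells. Lists were tested with camera in limma, which compares a list with all other genes, at its preset correlation of 0.01 between genes and with Benjamini-Hochberg adjustment over the 41 lists. Further tests were camera with a correlation estimated from the 10 libraries and fry, which asks only whether a list's members move, on balance, in a given direction. Members were counted at the threshold over all genes and, separately, adjusted over the list alone. Some genes were also members of another list, among them 9 of 26 tested p53 genes and 12 of 25 atrophy genes. Results of such lists are therefore not independent.

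Genes named in the text followed a rule fixed in advance, apart from changes given below. It takes Arrdc2, Arrdc1, Arrdc3, Arrdc4, Txnip, Fbxo32, Trim63, Myog and Myh4 whatever their values, and the 10 largest rises and 10 largest falls among called genes with a mean rlog of at least 5 whose groups do not overlap, leaving out clone and model names. From each list it takes members with the largest absolute log2 change among those called, 3 from a list that camera called and 2 from any other, or the member with the smallest p where none was called. The rule as fixed in advance allowed more than 3 from a list that camera called, and that number was lowered later. Members that make up a count of 5 or fewer are named too, and those outside the rule were chosen after their values were seen. A few genes that these rules select are counted in their lists but not reported singly.

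The methods were tested on data simulated from the recovered mean reads and size factors. For a simulated Arrdc2 against GFP comparison of 15230 genes, limma on simulated rlog values called 26%, 58%, 88% and 92% of 50 genes each changed 1.1-fold, 1.2-fold, 1.5-fold and 2-fold, and 3 unchanged genes. The median rlog folds of those genes were 1.07, 1.11, 1.22 and 1.57. Of 41 simulated lists with no change, camera called 0. Genes were simulated independently of each other, so this does not test lists whose genes vary together. Limma called 135 simulated genes in all, against 4616 in the real data, and the adjustment of p-values depends on that number. Each simulated gene was also given the typical spread of its level. The simulated shares and false calls therefore do not carry over directly to the real comparison. All simulated reads were recovered exactly, but the simulated values were made with the same penalised fit and settings that the recovery inverts. That result therefore tests only the solving step. Alternatives fixed in advance were other filters, prior variances, scalings, library weights, a minimum log2 change of 0.2 (treat), each library left out in turn, and other list tests. Those added later were voom on recovered reads with recovered size factors or total reads, voom after thinning to equal depth, and removal of a GC and length trend. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and reads were recovered with numpy 2.4.6 and scipy 1.17.1.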

Results

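RNA was sequenced from C2C12 myotubes 48 h after transduction with adenovirus carrying Arrdc2 and Gfp or Gfp only, with 5 libraries per group. Arrdc2 encodes an alpha-arrestin, a member of a family of adaptor proteins that link membrane proteins to ubiquitin ligases. The series' title describes the gene as induced in muscle by disuse and as able to reduce myotube diameter. The comparison asks which transcripts differ when Arrdc2 is delivered to differentiated myotubes. Depth, recovered from the deposited values, was 21.15, 18.93, 26.02, 23.29 and 22.46 M reads in GFP libraries 3 to 7, and 26.81, 24.43, 24.67, 28.65 and 23.50 M reads in Arrdc2 libraries 6, 7, 9, 10 and 11. Mean depth was 22.37 ± 2.62 M reads in GFP and 25.61 ± 2.09 M reads in Arrdc2 (SD, n = 5 each; exact 2-sided permutation p = 0.0714).

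Arrdc2 transcript itself was only modestly higher in the Arrdc2 libraries. Normalised reads counted to the mouse gene (ENSMUSG00000002910.12) were 90.4, 124.3, 109.2, 99.6 and 89.8 in GFP libraries 3 to 7, and 128.3, 123.3, 158.3, 118.05 and 132.5 in Arrdc2 libraries 6, 7, 9, 10 and 11. The means were 102.7 ± 14.5 reads in GFP and 132 ± 15.6 reads in Arrdc2 (SD, n = 5 each), a 1.29-fold difference with a 95% interval of 1.09 to 1.51. On the deposited log2 scale Arrdc2 rose by 0.11 ± 0.03 (SE; limma adjusted p = 0.0178; exact 2-sided permutation p = 0.0238), and 3 of the 5 Arrdc2 libraries lay above the highest GFP library. The call was lost without GFP library 3 (limma adjusted p = 0.0501), without GFP library 7 (0.0520) or without Arrdc2 library 9 (0.0570), within a range of 0.00832 to 1 over all alternatives. Whether transgene transcripts were counted to this gene is not given in the sources used here.

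Of the other alpha-arrestins, Arrdc3, Arrdc4 and Txnip fell. Arrdc3 fell from 1122 ± 92.5 to 788 ± 89.5 normalised reads (SD, n = 5), a 1.42-fold difference (log2 change −0.34 ± 0.05 SE, limma adjusted p = 2.86e-05). Arrdc4 was 1.502-fold lower (limma adjusted p = 0.00109), and Txnip, which binds thioredoxin and restrains glucose uptake, was 1.22-fold lower (limma adjusted p = 0.000191). For all 3 genes each Arrdc2 library lay below every GFP library. Arrdc1 was not called (1.13-fold, 95% interval 0.969 to 1.32, limma adjusted p = 0.211). Of 6 tested arrestin genes in the fixed list, which leaves out Arrdc2, 3 fell and 2 rose (the beta-arrestins Arrb1, 1.24-fold, and Arrb2, 1.21-fold), with the same counts adjusted over the list alone, and camera did not call the list (adjusted p = 0.608). Another list held NEDD4-family ligases, known partners of alpha-arrestins, and the adaptors of these ligases. Of 10 genes 2 fell (Smurf2, 1.19-fold, and Smurf1, 1.13-fold) and 1 rose (the adaptor Ndfip2, 1.09-fold). Its counts were the same adjusted over the list alone (camera adjusted p = 0.779).

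**Figure D1:**
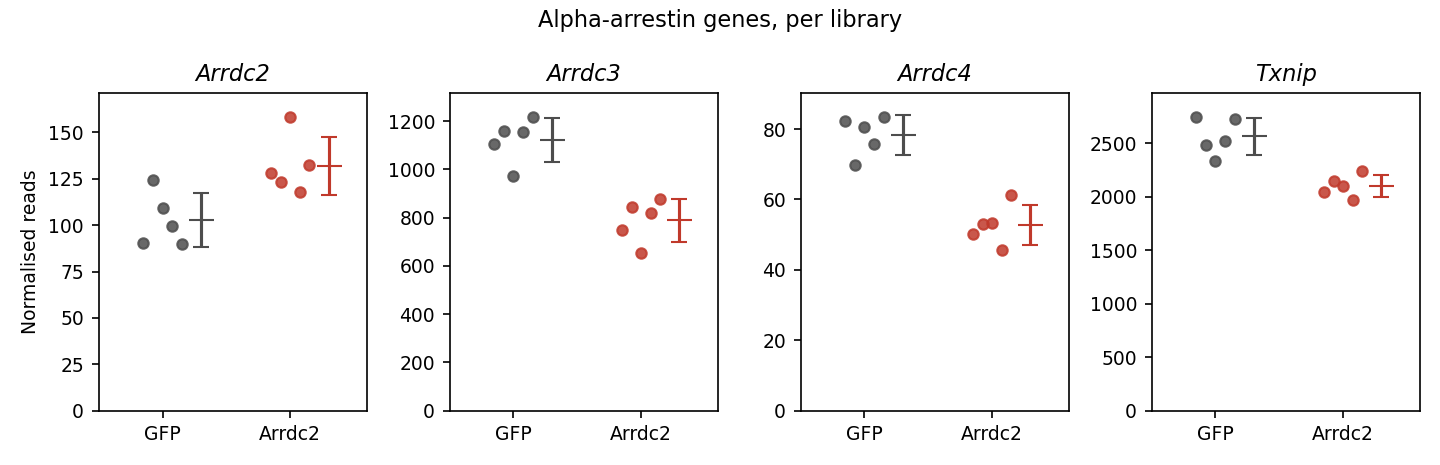
Normalised recovered reads of Arrdc2, Arrdc3, Arrdc4 and Txnip (vertical axes, from 0) in the 5 GFP and 5 Arrdc2 libraries. Points are libraries, and the bars to their right are the mean ± SD; Arrdc2 means were 102.7 and 132.1, while the Arrdc3, Arrdc4 and Txnip points of the groups do not overlap.

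Stress response, ribosomal protein, proteasome and sarcomere genes were among the falls, and interferon-induced, sterol synthesis and cell division genes were among those that rose. Ranked on the deposited log2 scale, the largest falls under the naming rule were Hspa1b, an inducible heat shock chaperone, from 3579 ± 102 to 955 ± 108 normalised reads (3.77-fold lower, 95% interval 3.45 to 4.12), and Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, from 3144 ± 251.7 to 945 ± 62.3 (3.33-fold lower). They were followed by Ccn2, a secreted matricellular protein (2.44-fold lower), Atf3, a stress-induced transcription factor (2.42-fold), Hspa1a (3.03-fold), Hsph1 (2.10-fold), Hspb1 (2.04-fold) and the cystine transporter Slc7a11 (2.41-fold). Then came Ccn1, also a secreted matricellular protein (2.02-fold), and Xirp2, an actin-binding protein of muscle (2.27-fold). Hspa1a and Hspa1b have nearly identical sequences, so the share of reads given to each is uncertain. The largest rises on the same scale, listed here by recovered fold, were Mest, from 520.1 ± 51.2 to 989.6 ± 64.04 normalised reads (1.90-fold, 95% interval 1.73 to 2.09), Mrgprf (1.87-fold), the interferon-induced Ifit1 and the integrin subunit Itga4 (both 1.78-fold), Serpinb8 (1.74-fold), Lrrc17 (1.68-fold), Tcim (1.57-fold), Cbr2 (1.56-fold), Lgals3bp (1.55-fold) and Olfml2b (1.48-fold). Folds here are from recovered reads and give another order, in which Cxcl1 (3.09-fold lower), Smad7 (2.15-fold lower) and Mstn (1.83-fold higher) would rank above several of them. Voom calls on recovered reads included 40 rises of at least 2-fold, each larger than any rise named here. By the naming rule, every one of these 20 genes had non-overlapping groups. Their limma adjusted p-values ran from 7.31e-14 for Hspa1b to 0.000457 for Lgals3bp.

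Of 15223 tested genes, limma called 4616 (30.3%), of which 2212 were higher and 2404 lower in the Arrdc2 libraries. Changes were mostly small, with a median of 19.9% in recovered reads among called genes. Voom on recovered reads called 4564 genes, 4533 of them shared with the deposited-value test in the same direction. Of its calls, 244 rose and 296 fell by at least 1.5-fold, and 40 rose and 80 fell by at least 2-fold. Groups did not overlap for 3005 genes (19.7% of those tested, against 0.794% by chance). Principal component 1 held 56.2% of the variance and separated the groups. The balance of directions moved with scaling: rises made up 47.9% of calls with the deposited values, 37.4% (1766 higher, 2960 lower) with each library centred on its median, and 63.3% (3063 higher, 1774 lower) by voom with total reads. Against a minimum log2 change of 0.2 on the shrunken scale, treat called 151 genes, 23 of them higher.

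**Figure D2:**
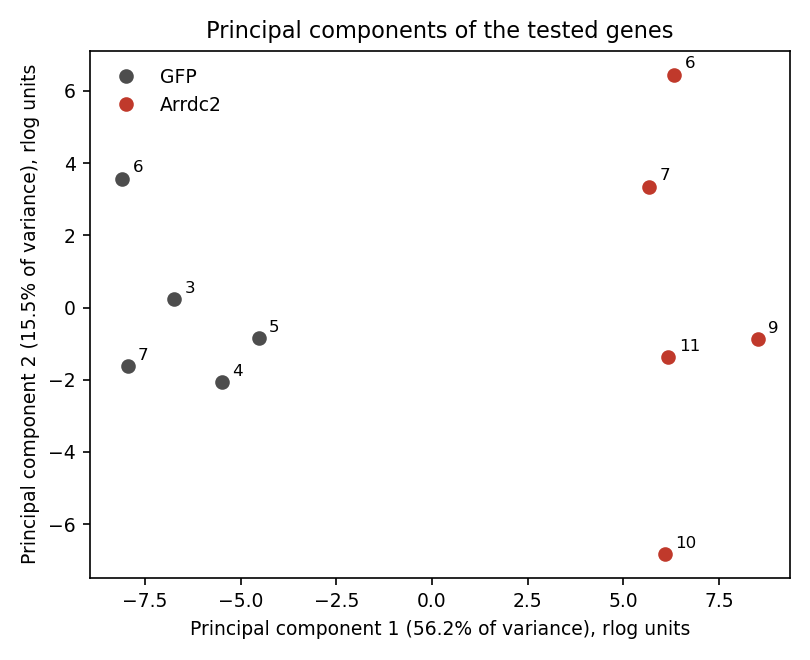
Principal components 1 and 2 of the 15223 tested genes (rlog units; 56.2% and 15.5% of the variance). Each point is a library with its column number; the 5 GFP libraries lie left of 0 on component 1 and the 5 Arrdc2 libraries right of it.

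Cytosolic heat shock proteins fell as a group. Of 22 tested members 17 fell and 1 rose (Hspb6, 1.26-fold), and 18 fell and 1 rose adjusted over the list alone. Camera called the list lower (adjusted p = 2.79e-20; adjusted p = 0.00279 with an estimated correlation). Hsph1 fell from 13953 ± 522 to 6640 ± 262 normalised reads, with a log2 change of −0.85 ± 0.03 (SE, limma adjusted p = 4.47e-13). Genes of the integrated stress response, most of them targets of the transcription factor ATF4, were also lower. Of 37 tested 36 fell and 0 rose, the same adjusted over the list alone (camera adjusted p = 1.56e-29, but adjusted p = 0.127 with an estimated correlation). Besides Atf3 and Slc7a11, the pseudokinase Trib3 fell from 2866 ± 332 to 1422 ± 149.7 normalised reads (2.01-fold, limma adjusted p = 1.59e-08).

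Targets of NRF2, the regulator of antioxidant enzymes, were also lower, with 16 of 32 falling and 4 rising (Gpx1, Gstm1, Keap1 and G6pdx, 1.084-fold to 1.22-fold), the same counts adjusted over the list alone (camera adjusted p = 3.18e-05, but adjusted p = 0.127 with an estimated correlation). Gclm, a subunit of the enzyme that limits glutathione synthesis, was 1.86-fold lower and the heme oxygenase Hmox1 1.62-fold lower. The p53 list had 10 falls and 3 rises (Pidd1, Trp53inp1 and Btg2, 1.21-fold to 1.27-fold) among 26, and 12 falls and 4 rises adjusted over the list alone (camera adjusted p = 0.0309, but adjusted p = 0.388 with an estimated correlation). Plk2 (1.74-fold), Gadd45a (1.42-fold) and Sesn2 (1.39-fold) fell. The p53 call was also lost without GFP library 4 (camera adjusted p = 0.0627), without Arrdc2 library 6 (0.0578), and in 3 other settings, within a range of 0.00984 to 0.388 over its camera alternatives (fry adjusted p = 0.000274). The list of endoplasmic reticulum chaperones and unfolded protein response genes went both ways. Of 26 genes 6 fell, among them Hspa5 (1.31-fold) and Hyou1 (1.21-fold), and 4 rose (Pdia6, Sec61b, Sdf2l1 and Eif2ak3, 1.09-fold to 1.32-fold). Its counts were the same adjusted over the list alone (camera adjusted p = 0.779).

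**Figure D3:**
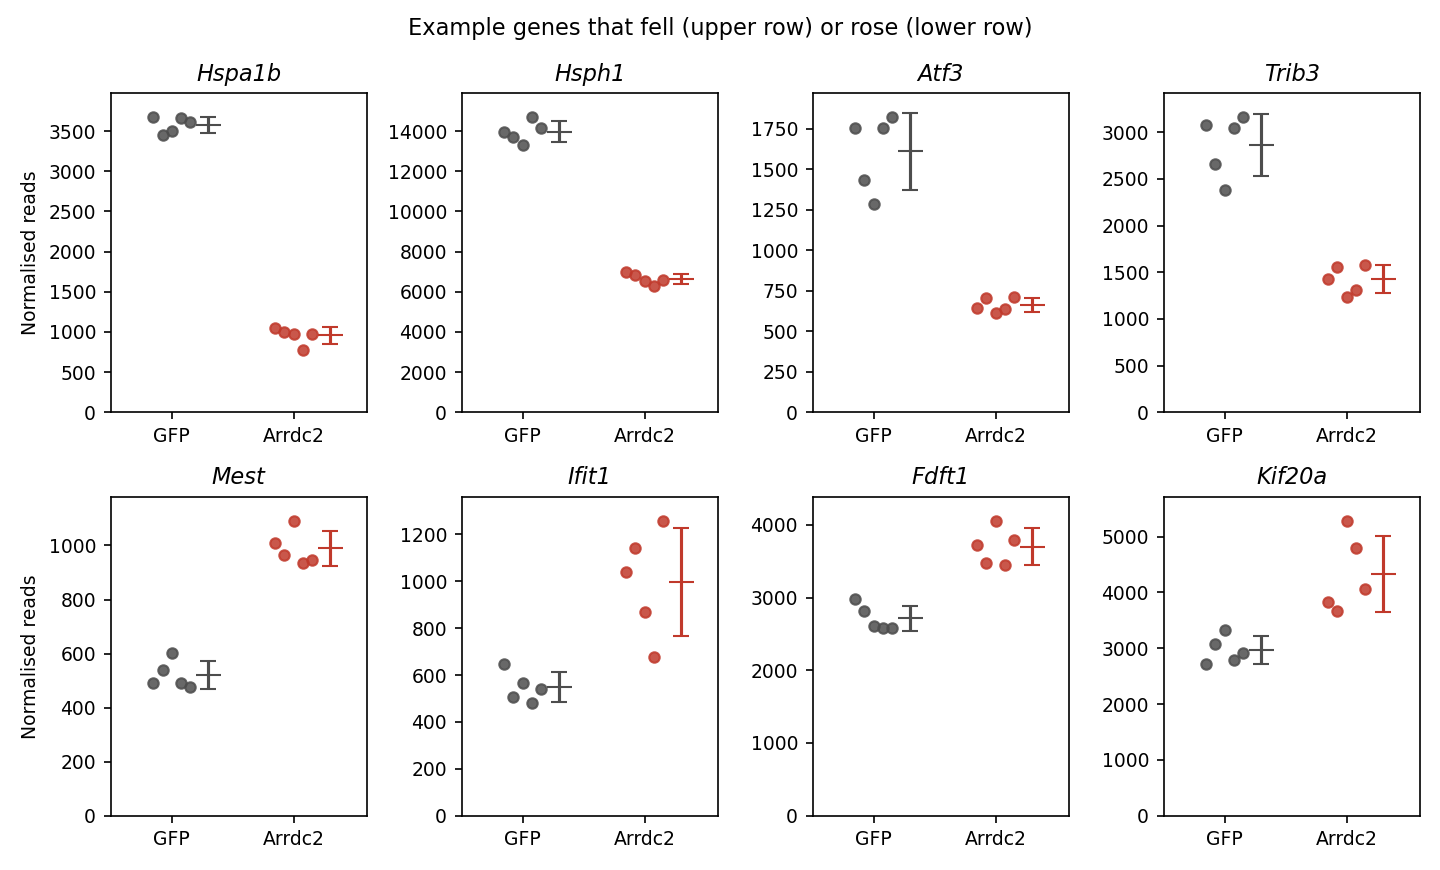
Normalised recovered reads (vertical axes, from 0) of 4 genes that fell (Hspa1b, Hsph1, Atf3, Trib3; upper row) and 4 that rose (Mest, Ifit1, Fdft1, Kif20a; lower row). Points are the 5 libraries of each group with the mean ± SD to their right; the groups of each gene do not overlap.

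Cytosolic ribosomal proteins fell by small amounts. Of 49 members 32 fell and 0 rose, and 36 fell adjusted over the list alone (camera adjusted p = 9.79e-11, but adjusted p = 0.424 with an estimated correlation). By mean rlog value of the list, Arrdc2 library 10 (12.447) lay close to the lowest GFP library (12.449), and the other Arrdc2 libraries lay at 12.30 to 12.37. Rpl3 and Rpl30 were both 1.23-fold lower and Rpl27 1.21-fold lower. Subunits of the 26S proteasome, the protease of ubiquitin-tagged proteins, fell in 22 of 31 cases and rose in 0, with 24 falls adjusted over the list alone (camera adjusted p = 1.55e-08, but adjusted p = 0.388 with an estimated correlation). Psmd14 (1.19-fold), Psma5 (1.18-fold) and Psmb7 (1.17-fold) changed most.

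NF-kappaB targets, cytokines and chemokines included 10 falls and 3 rises (Il15 1.49-fold, Ccl7 1.52-fold, Cxcl12 1.16-fold) among 24, and 10 falls and 4 rises adjusted over the list alone (camera adjusted p = 0.0273, but adjusted p = 0.134 with an estimated correlation). Besides Ptgs2, the growth factor Csf1 fell from 3518 ± 152 to 2244 ± 94.4 normalised reads (1.57-fold) and the chemokine Cxcl1 from 102.9 ± 8.47 to 33.8 ± 8.60 (3.09-fold). In the TGF-beta list, 6 of 27 genes fell, led by Ccn2 and the pathway inhibitor Smad7 (2.15-fold lower), and 4 rose (Bmp4, Tgfbr2, Gdf11 and Mstn, 1.12-fold to 1.83-fold), the same adjusted over the list alone (camera adjusted p = 0.208).

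Camera called the sarcomere list lower and no other list of muscle genes. Of 51 sarcomere genes 19 fell and 0 rose, and 23 fell adjusted over the list alone (camera adjusted p = 1.93e-05, but adjusted p = 0.276 with an estimated correlation). Those with the largest falls were Xirp2, Xirp1 (1.39-fold) and Cryab, a small heat shock protein of the Z-disc (1.51-fold), so the list's leading members are stress-responsive or repair-associated proteins as well as structural ones. The fast myosin Myh4 was not called (8586 ± 476 and 9707 ± 1403 normalised reads, limma adjusted p = 0.0874), nor was Myog, a regulator of differentiation (7429 ± 708 and 6567 ± 936, limma adjusted p = 0.0748). Without Arrdc2 library 10, limma called Myh4 higher (adjusted p = 0.00628) and Myog lower (adjusted p = 0.00252). Limma also called Myh4 higher in 4 other alternatives (quantile normalization, library weights, voom with total reads, GC and length correction; adjusted p = 0.0201 to 0.0424). It called Myog lower with median centring (adjusted p = 0.0447) and library weights (adjusted p = 0.0266). Among 19 myogenic regulators 3 rose (Myf5 1.17-fold, Pax7 1.24-fold, Eya1 1.16-fold) and 1 fell (Des, 1.101-fold), the same adjusted over the list alone (camera adjusted p = 0.631). Excitation-contraction coupling genes numbered 4 falls (Jph2 and Casq1, both 1.19-fold, Casq2 and Jph1) and 3 rises (Bin1, Itpr1 and Stac3) of 24, the same adjusted over the list alone (camera adjusted p = 0.760). At the neuromuscular junction 5 of 17 fell (among them Lrp4, Ncam1, Dok7 and Musk) and 2 rose (Ache and Chrnd), the same adjusted over the list alone (camera adjusted p = 0.670). The call of Lrp4 was lost without any of GFP libraries 4, 5 and 6 or Arrdc2 libraries 9, 10 and 11 (limma adjusted p = 0.0612 to 0.112), and in 7 other settings (0.0711 to 1).

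Genes associated with muscle wasting moved in both directions. Fbxo32, the ubiquitin ligase atrogin-1, rose from 1484 ± 101 to 1720 ± 180.1 normalised reads (1.16-fold, log2 change 0.15 ± 0.05 SE, limma adjusted p = 0.0172; 3 of 5 libraries above the highest GFP library), whereas Trim63, the ligase MuRF1, fell from 1525 ± 53.8 to 1339 ± 97.6 (1.14-fold, limma adjusted p = 0.00718; 5 of 5 below the lowest). The Fbxo32 call was lost without GFP library 5 (limma adjusted p = 0.0504) or Arrdc2 library 7 (0.0540), with no filter on low values (0.0632) and with treat (1). Of 25 atrophy genes 9 fell, led by Gadd45a (1.42-fold), and 5 rose (Bnip3 1.47-fold, Mstn 1.83-fold, Ddit4, Fbxo32, Ampd3), with 10 and 6 adjusted over the list alone. Camera did not call the list (adjusted p = 0.288), whereas fry, which does not compare it with other genes, called it lower (adjusted p = 0.00592). Autophagy and lysosome genes included 6 falls and 6 rises of 40, with 6 and 7 adjusted over the list alone (camera adjusted p = 0.779). The autophagy receptor Sqstm1 was 1.46-fold lower and the cholesterol exporter Npc1 1.22-fold higher.

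Interferon-stimulated genes rose. Of 43 tested 32 rose and 0 fell, and 34 rose adjusted over the list alone (camera adjusted p = 6.9e-12, but adjusted p = 0.388 with an estimated correlation). The mean rlog value of the list was 7.64, 7.63 and 7.68 in Arrdc2 libraries 6, 7 and 11, but 7.458 in library 9 and 7.440 in library 10, close to GFP library 3 (7.454). Ifit1 went from 548 ± 63.8 to 997 ± 229 normalised reads, Ifit2 was 1.52-fold higher and the signal transducer Stat2 1.46-fold higher. Genes of antigen presentation on MHC class I rose in 12 of 23 cases and fell in 0, with 13 adjusted over the list alone (camera adjusted p = 4.13e-06, but adjusted p = 0.0630 with an estimated correlation). Tapbp was 1.33-fold, H2-Q4 1.38-fold and H2-T23 1.35-fold higher, although reads are shared within the H2 family and the values of its single genes are uncertain.

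Camera called cholesterol synthesis, lipid synthesis and glycolysis lists higher. Of 24 genes of cholesterol synthesis 20 rose and 0 fell, and 22 rose adjusted over the list alone (camera adjusted p = 1.37e-11, but adjusted p = 0.276 with an estimated correlation); Stard4 (1.42-fold), Insig1 (1.36-fold) and the squalene synthase Fdft1 (2715 ± 176 to 3701 ± 251 normalised reads, 1.36-fold) led. In fatty acid synthesis and lipid storage 13 of 20 rose, among them Srebf1 and Fads2 (both 1.39-fold) and Scd2 (1.38-fold), and 1 fell (Angptl4, 1.28-fold), with 14 and 2 adjusted over the list alone (camera adjusted p = 1.38e-05, but adjusted p = 0.276 with an estimated correlation). Arrdc2 library 10 lay close to GFP library 3 in mean rlog value for cholesterol synthesis (11.035 and 11.025) and for lipid synthesis (10.749 and 10.742), while the other Arrdc2 libraries lay at 11.15 to 11.24 and at 10.85 to 10.93. Glycolysis had 13 rises and 1 fall (Hk2, 1.23-fold) among 27 gene identifiers, of which a pair share the symbol Aldoa, and 17 and 1 adjusted over the list alone (camera adjusted p = 1.18e-05, but adjusted p = 0.127 with an estimated correlation). The lactate transporter Slc16a3 was 1.37-fold, Pfkl 1.34-fold and Hk1 1.31-fold higher. For the citric acid cycle and fatty acid oxidation 8 of 31 rose, with Idh2 (1.31-fold) and Ucp2 (1.14-fold) foremost, and 1 fell (Pdhb, 1.11-fold), the same adjusted over the list alone (camera adjusted p = 0.0819). Of 49 nuclear respiratory chain genes 3 fell (Cox6a2 1.23-fold, Uqcrb, Ndufa10) and 2 rose (Cox8a and Ndufb8), with 1 and 0 adjusted over the list alone (camera adjusted p = 0.8996). Uqcrb lost its call without any of GFP libraries 3, 6 and 7 or Arrdc2 libraries 6, 7, 9 and 11 (limma adjusted p = 0.0553 to 0.142), and in 7 other settings (0.0505 to 1). None of 7 mitochondrial genes was called over all genes or adjusted over the list alone (mt-Nd6, 1326 ± 54.4 and 1167 ± 166 normalised reads, limma adjusted p = 0.0507; camera adjusted p = 0.608 for the list). Limma called mt-Nd6 lower with median centring (adjusted p = 0.0282) and without GFP library 7 (0.0469), Arrdc2 library 6 (0.0289), Arrdc2 library 7 (0.0330) or Arrdc2 library 9 (0.0179).

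Proliferation genes rose, although myotubes themselves do not divide. Of 45 cell cycle genes 31 rose and 0 fell, and 36 rose adjusted over the list alone (camera adjusted p = 5.37e-10, but adjusted p = 0.465 with an estimated correlation). The mitotic kinesin Kif20a was 1.45-fold, Ube2c 1.37-fold and Cdk1 1.35-fold higher. Of 11 fibroblast markers 6 were not called, among them Col1a1 (7958 and 7650 normalised reads) and Vim (82332 and 82617). The other 5 rose (Dcn 1.34-fold, Ly6a 1.24-fold, Col3a1 1.21-fold, Pi16, Dpt) and 0 fell, the same adjusted over the list alone (camera adjusted p = 0.0309, but adjusted p = 0.388 with an estimated correlation). That call was lost without GFP library 4 (camera adjusted p = 0.0608; range over camera alternatives 0.00807 to 0.388; fry adjusted p = 0.00801). By mean rlog value of the list, GFP library 5 (10.193) lay above Arrdc2 libraries 7, 10 and 11 (10.173 to 10.189), and GFP libraries already held 42427 ± 2606 normalised reads of Col3a1. Genes of undifferentiated myoblasts included 6 rises, led by Heyl (1.47-fold) and the receptor Fgfr4 (1.51-fold), and 1 fall (Sdc4) of 17, with 7 and 3 adjusted over the list alone (camera adjusted p = 0.0789). The cell cycle rise was uneven: the mean rlog value of the list was 10.61 in both Arrdc2 libraries 9 and 10, whereas Arrdc2 libraries 6 (10.395) and 7 (10.388) lay below GFP library 5 (10.404).

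Tested markers of other cell types ranged widely in level, from 9.29 normalised reads of Mbp to 36264 of Spp1 in GFP libraries. Many fixed markers were not among the tested genes, which needed a symbol and a mean rlog of at least 3. Tested were 5 of 10 endothelial, 6 of 10 neural, 3 of 11 adipocyte, 4 of 11 osteoblast and 3 of 12 macrophage markers. Of 5 endothelial markers 3 rose (Vwf, 67.7 ± 7.29 to 96.2 ± 9.67 normalised reads; Tek; Cldn5; camera adjusted p = 0.131), and of 6 neural markers 1 rose (Map2 1.38-fold, camera adjusted p = 0.608). Among 3 adipocyte markers Pparg fell 1.18-fold and Lpl rose 1.096-fold (camera adjusted p = 0.806), the latter not called without any of GFP libraries 3, 4, 5 and 6 or Arrdc2 libraries 6 and 7 (limma adjusted p = 0.0549 to 0.113) nor in 4 other settings (0.0697 to 1). None of 4 osteoblast markers (Bglap2, 34.1 ± 5.88 and 43.9 ± 8.38 normalised reads, limma adjusted p = 0.113; camera adjusted p = 0.898 for the list) or 3 macrophage markers (Cd14, 80.6 ± 14.8 and 98.3 ± 8.36, limma adjusted p = 0.0712; camera adjusted p = 0.617 for the list) was called. Limma called Bglap2 higher without Arrdc2 library 9 (adjusted p = 0.0385) and Cd14 higher without GFP library 4 (adjusted p = 0.0152) and by voom with total reads (adjusted p = 0.0317). All counts of these 5 lists were the same adjusted over the list alone.

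**Figure D4:**
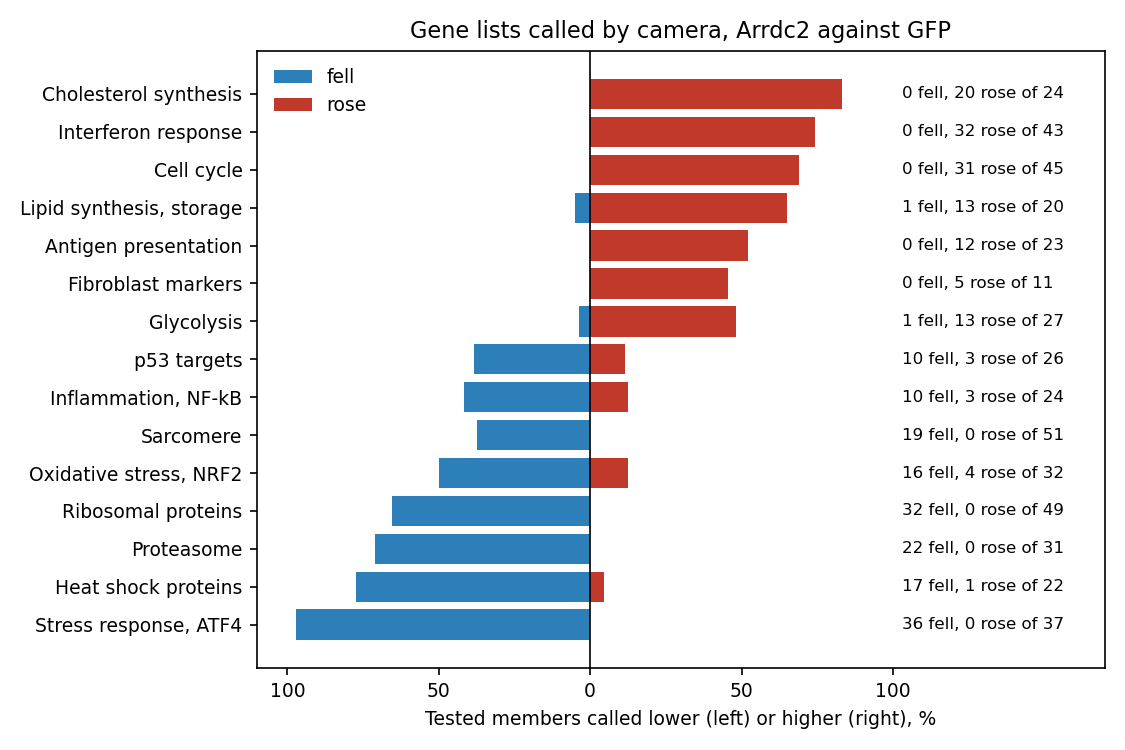
Share of each list's tested members that fell (bars to the left, %) or rose (bars to the right, %) for the 15 lists called by camera, with the counts beside the bars. The ATF4 list lies lowest, with 36 of 37 members falling, and cholesterol synthesis highest, with 20 of 24 rising.

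Signalling and housekeeping lists not called by camera also held called genes. Limma called 30.3% of all tested genes, so some called members are to be expected in any list. For apoptosis, 8 of 28 rose, among them Bmf (1.48-fold), and 3 fell (Mcl1, Bcl2l1 and Bcl2), with 9 and 3 adjusted over the list alone (camera adjusted p = 0.124). Of 40 matrix genes 9 rose, including Dcn and Thbs2 (1.2998-fold), and 7 fell (camera adjusted p = 0.8996), and of 24 Notch and Wnt genes 10 rose, led by Heyl, and 2 fell (Jag1 1.38-fold, Wnt5a) (camera adjusted p = 0.0942). For the clock 8 of 18 fell, foremost Nfil3 (1.40-fold) and Cry2 (1.37-fold), and 2 rose (Npas2 and Per3; camera adjusted p = 0.124). Counts of these 3 lists were the same adjusted over the list alone. In the insulin and mTOR list 5 of 31 rose (Igfbp5 1.29-fold, Igf1, Igf2r, Ddit4, Igfbp3) and 5 fell (Irs2 1.47-fold, Deptor, Eif4ebp1, Igf1r, Foxo1), with 6 and 5 adjusted over the list alone (camera adjusted p = 0.779). In the beta-adrenergic list 3 of 23 rose (among them Rgs2 1.48-fold and Prkar1a) and 4 fell (Sik1 1.199-fold, Nr4a1, Nr4a2, Nr4a3, camera adjusted p = 0.779). Endocytosis genes had 5 rises (Ap2s1 1.21-fold, Ap2a1, Ap2b1, Eps15, Clta) and 5 falls (Eea1 1.24-fold, Vps37b, Rab5a, Vps4b, Chmp4b) of 38 (camera adjusted p = 0.8996). Among 11 genes that neighbour Arrdc2 in the genome, 4 rose (Ifi30 1.297-fold, Pik3r2 1.22-fold, Mast3, Rab3a) and 1 fell (Slc5a5; camera adjusted p = 0.306); these 3 lists kept their counts adjusted over the list alone. Median, mean and test differed in sign for 5 lists, none called. These were the unfolded protein, NEDD4-family, endocytosis, matrix and nuclear respiratory chain lists.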

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

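Of the tests in this part, those on the Arrdc2 level, on untransduced cultures and on sarcomere against coupling genes were chosen after the result was seen, and thinning and GC correction were alternatives added after seeing the data; the splits of the libraries were planned.

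Single libraries stood apart from the rest of their group for 14 of 298 group and value pairs, where chance gives about 14.9. The measure is the gap to the nearest other library as a share of the group's range. In GFP, library 7 was lowest for Pax7 (share 0.742; rlog 8.08, nearest 8.21), library 5 highest for Ucp2 (0.715; 10.77, nearest 10.68) and Thbs2 (0.747; 10.94, nearest 10.73), and library 3 highest for Fads2 (0.769; 11.94, nearest 11.85). In Arrdc2, library 10 was lowest for Mrgprf (0.777; 8.70, nearest 9.02), Cbr2 (0.771; 10.96, nearest 11.16), Hspa1b (0.768; 9.98, nearest 10.21) and Tapbp (0.724; 11.42, nearest 11.58), and highest for Rpl27 (0.839; 11.14, nearest 11.01). Arrdc2 library 9 was lowest for Trim63 (0.787; 10.28, nearest 10.43) and highest for Lrrc17 (0.765; 10.86, nearest 10.66) and Stard4 (0.823; 10.73, nearest 10.52), while library 6 was lowest for Psmd14 (0.832; 11.62, nearest 11.69) and highest for Lpl (0.821; 9.82, nearest 9.73).

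The 4616 genes called between the groups were not matched by any other of the 100 splits of the 10 libraries into 5 and 5 that were drawn from 126. Only 1 split, the real one, reached that number, and limma called 0 genes in the others. Every other split mixes libraries of both groups, so the group difference adds to its spread and lowers its calls. The real division thus stands apart from the others drawn. The splits cannot tell an effect of the virus from a chance difference between cultures, as the replicates may be technical. At an unadjusted p under 0.05, the real split gave 6211 genes and the highest other split 3274; other tools were not run on the splits.

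Arrdc2 reads were less than 2-fold higher in libraries described as receiving an Arrdc2 virus. Shrinkage in the deposited values did not hide a large increase, because the upper 95% bound of the fold in recovered reads was 1.51. A swap of single libraries between the groups is argued against too, since 0 libraries lay on the other group's side of principal component 1, a count that an exchange of the whole groups would leave as it is. A transgene whose transcript is not counted to mouse Arrdc2 (another species, or a coding sequence the counting missed) cannot be told apart from weak expression, because 0 rows of the table are anything but mouse genes. Protein was not analysed here, so how much Arrdc2 the cells held stays open.

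Heat shock and ATF4 target genes were lower in the Arrdc2 libraries, with a median log2 change of −0.47 over 59 members in recovered reads; with an estimated correlation camera kept the heat shock call (adjusted p = 0.00279) and lost the ATF4 call (adjusted p = 0.127). After thinning to equal depth the median was −0.47 (95% bootstrap interval −0.52 to −0.41). Thinning keeps each gene's expected normalised fold, so it could hardly have moved this median and does not decide whether unequal depth contributed. Removing a trend on GC content and transcript length left the rlog median at −0.35 (−0.35 before, interval −0.39 to −0.30), which argues against such a trend as the whole cause. Both intervals resample genes as if independent, which they are not. An action of Arrdc2 may lower these genes, or the Gfp-only virus may raise them: the readings cannot be told apart, since 0 libraries of untransduced cultures were used here. Virus dose per group is not given in the sources used here and was not tested.

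The sarcomere list was lower and the cell cycle list higher, calls that camera lost with an estimated correlation (adjusted p = 0.276 and 0.465), and a smaller share of myotubes in the cultures could produce both. That would lower excitation-contraction coupling genes alike, but the 22 coupling genes outside the sarcomere list had a mean recovered log2 change of −0.0048, against −0.15 for 49 sarcomere genes outside the coupling list (2-sided permutation p = 0.00417, 100000 resamples). This does not exclude a smaller share, because the coupling list had both rises (3) and falls (4) and the test treats genes as independent, which they are not. By library, the mean rlog value of the coupling list was 11.28, 11.25 and 11.27 in Arrdc2 libraries 9, 10 and 11, below the lowest GFP library (11.30), but 11.39 and 11.35 in Arrdc2 libraries 6 and 7. A smaller share of myotubes, a change within myotubes and a change within dividing mononucleated cells all stay open.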

How the results depend on the processing

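Voom on recovered reads, thinning and GC correction were added after seeing the data. No paired analysis was possible because the columns of the table carry library numbers that do not match the replicate numbers of the labels, so the replicate block was not run. No count of changed genes moved by over 1.5 times except with a minimum log2 change of 0.2, where limma's treat called 151 genes (23 higher, 128 lower) in place of 4616; fewer genes pass because the shrunken changes are small. Without each library in turn, 3920 to 4598 genes were called. No call of a named gene or list reversed in the alternatives run on it. Of 101 called named genes, 95 kept their call in all alternatives but that minimum; among the 6 others were Arrdc2, Fbxo32, Lrp4, Uqcrb and Lpl.

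The Arrdc2 call was lost with quantile normalization (log2 change 0.086), the minimum change (0.11) and thinned voom (0.32); leaving out libraries gave 0.085 to 0.13. The cause was not tested.

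Of 15 called lists, camera with an estimated correlation kept 1 (heat shock) and lost 14. Adjusted p-values were then 0.0630 for antigen presentation, 0.127 for ATF4, NRF2 and glycolysis, 0.134 for NF-kappaB, 0.276 for sarcomere, cholesterol and lipid synthesis, 0.388 for proteasome, interferon, p53 and fibroblast lists, 0.424 for ribosomal proteins and 0.465 for cell cycle. Against the preset 0.01, the estimate was 0.0455 for heat shock, 0.474 for ATF4, 0.616 for interferon, 0.624 for ribosomal proteins and 0.742 for cell cycle. For such lists the preset lies far below the estimate. Antigen presentation (0.0319) and NF-kappaB (−0.0035) lost their calls at low estimates, so a high correlation does not account for every loss. Fry called 24 lists, 9 of them not called by camera. Of these the arrestin, atrophy, TGF-beta and clock lists were lower. The apoptosis, myoblast, endothelial, neural and Arrdc2 neighbour lists were higher. Fry does not compare a list with other genes. The p53 list also lost its call with a mean rlog of at least 5 (0.0573), median centring (0.0594) and quantile normalization (0.0811), and ranged from 0.0160 to 0.0627 without each library. The fibroblast list lost its call with a mean of at least 5 (0.0700) and ranged from 0.00807 to 0.0608 without each library. For both, the cause was not tested. The other 13 lists were lost only with the estimated correlation or, for heat shock, never. Of uncalled lists, 4 were called in some setting other than fry (citric acid cycle, apoptosis, Notch and Wnt, myoblast genes). Arrdc2 had 79 to 166 reads per library, and which fold can be resolved at that depth was not tested.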

Other observations

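Genes that build ribosomes and load tRNAs were lower in the Arrdc2 libraries. These lists, like those of immediate early genes and YAP targets, were chosen only after the result was seen, and the genes that prompted them were left out of the tests. Of 34 nucleolar ribosome biogenesis factors 33 fell and 0 rose, with 34 falls adjusted over the list alone; the nucleolar proteins Npm1, Tsr1 and Nop56 were 1.49-fold, 1.502-fold and 1.48-fold lower. Of 15 cytosolic aminoacyl-tRNA synthetases outside the ATF4 list 12 fell and 0 rose, with 13 falls adjusted over the list alone, led by Nars (1.46-fold). Among immediate early genes, which respond to growth factors and stress within minutes, 18 of 28 fell and 0 rose, with 18 falls and 1 rise adjusted over the list alone; the growth factors Ereg and Hbegf were 1.80-fold and 1.61-fold lower.

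Camera, adjusted over these 4 lists, called ribosome biogenesis (adjusted p = 3.92e-30; adjusted p = 0.0143 with an estimated correlation), tRNA synthetases (adjusted p = 2.46e-10; adjusted p = 0.0421 with an estimated correlation) and immediate early genes (adjusted p = 2.97e-08; adjusted p = 0.0143 with an estimated correlation). Targets of the coactivators YAP and TAZ were tested because Ccn1 and Ccn2 were among the largest falls. Ccn1, Ccn2 and Amotl2 were left out of this list. Of 20 other targets 7 fell (Ajuba, Crim1, Nuak2, Ankrd1, Lats2, Amotl1 and Rbms3) and 3 rose (Igfbp3, Ccdc80 and Myof). These counts were the same adjusted over the list alone. Camera gave the direction as lower but did not call the list (adjusted p = 0.0690). A missing call does not show that the targets were unchanged, so whether they fell as a group stays open.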
